A study of Drosophila melanogaster with 2 samples.

How the data were processed

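Poly(A) RNA of posterior midguts from wild-type Oregon R females was sequenced on an Illumina instrument at 2 ages, 5 days and 45 days, with 3 biological replicates per age, per the labels. Midguts were pooled before RNA extraction, per the labels' protocols, so each replicate averages over many animals, and p-values measure the spread between such pools. The aligner, the genome build and the rules for counting shared or antisense reads are not given in the sources used here, and the library kit is named without a strand setting. The submitters' processing notes name DESeq, with no version.

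The deposited transcript table holds raw read counts for 24047 transcripts in 6 columns, 3 named treatment and 3 named control by the authors. Neither the column names nor the labels say which set is which age. The values are therefore described throughout as treatment against control. If the control set is, as is usual, the younger age, "higher in treatment" reads as higher at 45 days, but nothing in the sources used here states this. The same deposited table gives a normalized signal per transcript, which per the file headers is reads per transcript length and per all mapped reads, and it was used only to work out the implied number of mapped reads. The deposited p-values of that table were not used for any call. A second deposited table by the authors gives a mean normalized signal, a log2 fold change with its standard error, and p-values for 4101 genes, all with an adjusted p of at most 0.0999. The direction formula in the authors' column descriptions reads control over treatment. Yet of the 3552 genes in that table that matched a gene tested here, 3547 carry the sign of treatment over control.

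Transcripts of one gene share reads in the transcript table. Of 2666 loci with several transcripts and at least 600 reads, 72.2% had a least-read transcript with at least 80 percent of the reads of the most-read one, and summed reads were a median of 2.0 times the top transcript's. Each of the 13822 loci was therefore represented by its most-read transcript over all 6 libraries, after 145 predicted transcripts were left out, and 6 loci whose symbol was already taken were dropped. Symbols came from the RefSeq gene table of the Release 6 assembly by NCBI gene ID for 12825 loci and from the deposited table otherwise. Coordinates are those of the deposited table, whose build is not named. Only 21.58% of 12820 loci start within 1000 bases of their Release 6 position, so no reference coordinate was mixed in. Loci whose symbols are merged in the deposited table, such as neighbouring or overlapping genes, were not matched to members of lists given by gene name. Lists filled by symbol prefix could take them in, as with Cyp6u1/CG30157 on the cytochrome P450 list.

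Reads summed over genes were 18001949, 9581958 and 11050821 in treatment replicates 1 to 3 and 12146646, 16739553 and 15623844 in the control replicates. Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, filterByExpr with a minimum count of 10, and the quasi-likelihood test of treatment against control with Benjamini-Hochberg adjustment at 0.05. All adjusted p-values are from edgeR, or from limma for gene lists, unless another tool is named. CPM values are TMM-scaled and are given as mean ± SD over 3 libraries, and log2 fold changes with their standard errors (SE).

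Before the data were examined, 38 gene lists were fixed from general knowledge: 26 of pathways and 12 of cell types, described in the report by name. Each was tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. Fry, which asks whether a list's genes move on balance in one direction and does not compare them with other genes, was also run. A list is said to pass where it passed camera at the preset correlation, unless fry is named. Members were counted over all genes tested and adjusted over the list alone. One member of the enteroendocrine list, dmGlut, entered through a mistaken alias of another transporter and is not an enteroendocrine marker. Lists filled by symbol prefix can also hold genes that only share the prefix, and these stay in the counts. Cyp1 and Cyp40 on the cytochrome P450 list are cyclophilin genes. RpL24-like on the cytosolic ribosomal protein list encodes a ribosome biogenesis factor.

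The genes named were chosen by a rule fixed beforehand: the 8 largest rises and 8 largest falls among changed genes with a mean normalized count of at least 50 and sets that do not overlap; up to 3 changed members of each list with the smallest adjusted p; and 12 genes named whatever their value (Gli, bark, M6, dlg1, esg, Delta, upd3, DptA, Duox, PGRP-SC2, foxo and pros). Other genes are said to be chosen after their values were seen.

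The procedure was tested on simulated counts drawn from the real means and library sizes. Among 8103 genes, edgeR called 64% of genes changed 1.3-fold, 90% of those changed 1.5-fold, 96% at 2-fold and 100% at 4-fold, and 6 of 7905 unchanged genes. Camera called 20 of 20 simulated lists of 20 genes in which every gene was raised 1.5-fold, and 0 of 20 unshifted ones. These lists were drawn without correlation between genes. Smaller shifts, as in most of the lists that passed in the real data, were not simulated.

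Alternatives were RLE size factors, no filter, a mean count of at least 100, a block on replicate number, leaving out each library, DESeq2 1.42.0, an adjusted p of 0.01, a change of at least 2-fold, transcripts in place of genes, centring on the median of all genes, an estimated correlation and, added after the TMM factors had been seen, scaling by total reads alone. Near-identical gene copies (the Jon25B, Jon65A, Jon66C and Jon99 proteases, LysB to LysE, PGRP-SC1a, actins, Hsp70 copies) may share reads, and their single values are uncertain.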

Results

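Transcript levels in the posterior midgut, the absorptive hind part of the fly's middle intestine, were compared between 2 sets of 3 libraries of wild-type females to ask what differs between guts of 5-day-old and 45-day-old flies. The sets are named treatment and control in the authors' table, and no source used here ties either name to an age. If control is the younger age, values higher in treatment are values higher at 45 days. Libraries held 9581958 to 18001949 reads over genes. Mitochondrial transcripts took 8.71%, 7.66% and 10.1% of the reads in the treatment libraries and 7.03%, 6.33% and 6.86% in the control libraries. Within a set, libraries differed by more than sampling noise (chi-square per degree of freedom of 2.45 to 7.64). Between sets the values were far higher (105 to 196). Each library was counted as 1 sample because the labels state 3 biological replicates per age, which these values cannot test.

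The 2 sets differed across much of the transcriptome, mostly by small amounts. Of 8137 genes tested, 4000 changed, 2038 higher and 1962 lower in treatment, with a median absolute log2 fold change of 0.41, and 590 changed at least 2-fold (196 higher, 394 lower). The sets did not overlap for 55.2% of genes, where chance gives 10%. With scaling by total reads alone, added after the scaling factors had been seen, the median of all genes shifted to 0.22 (0.01 with TMM) and the split became 4127 higher and 1076 lower. In the authors' deposited table, 3657 genes had an adjusted p under 0.05, 1789 with a positive and 1868 with a negative sign.

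Among genes with a mean normalized count of at least 50 and sets that do not overlap, the largest rise was in Vha100-4, a subunit of the proton-pumping V-ATPase (3R, 14212555 to 14215525, in the deposited table's unnamed build), at 29.0 ± 2.67 CPM in treatment and 1.06 ± 0.255 in control (mean ± SD, n = 3 each; 27.4-fold). CG5767 rose 21.7-fold, from 8.05 ± 0.231 to 175.0 ± 11.5 CPM, and CG8661 rose 11.1-fold. Further rises were ple, the tyrosine hydroxylase of dopamine and melanin synthesis (8.75-fold), CG34040 (7.88-fold), CG6271 (6.47-fold), tobi, an alpha-glucosidase (5.25-fold), and Tsf1, an iron-binding transferrin (5.24-fold). By the same criteria the largest fall was in CG5892 (3R, 17068351 to 17071140), from 43.0 ± 2.24 to 1.02 ± 0.300 CPM (log2 fold change -5.40, SE 0.13). The scavenger receptor gene ninaD, needed for carotenoid uptake, fell from 403.1 ± 6.92 to 26.8 ± 1.91 CPM (log2 -3.93, SE 0.06). CG9825 (-3.36), Lsd-1 (-2.91), Ugt37B1 (-2.80), the efflux transporter Mdr50 (-2.78) the protease Jon66Cii (-2.75) and CG13360 (7.99-fold lower) completed the 8 largest falls.

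**Figure D1:**
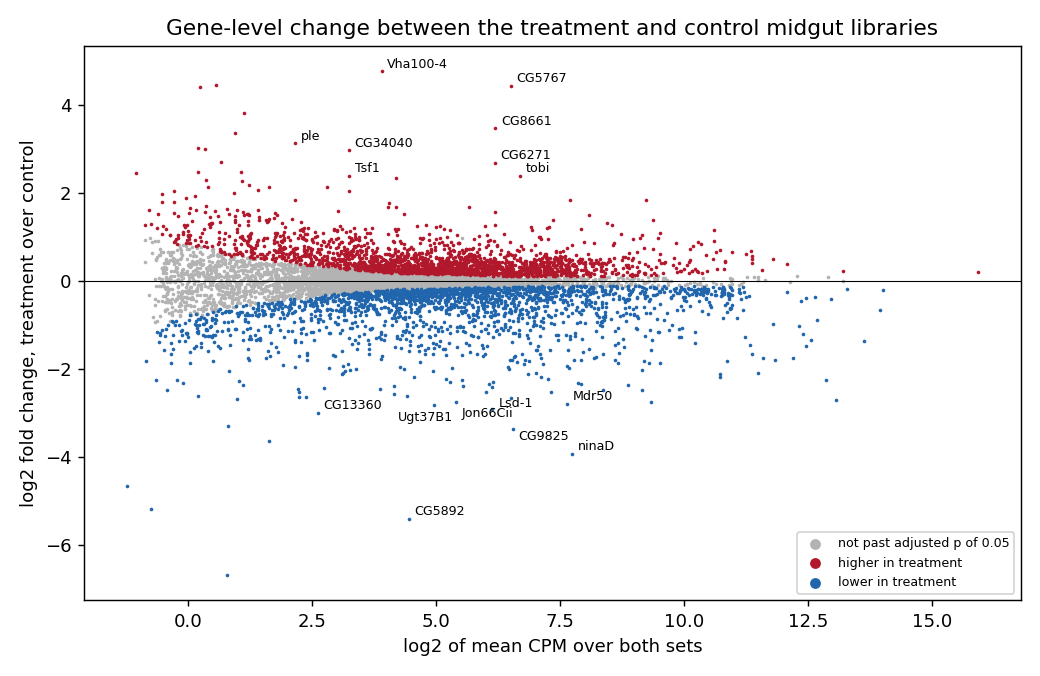
Log2 fold change (treatment over control) against log2 mean CPM for the 8137 genes tested, each point a gene, colored by whether and in which direction it passed an adjusted p of 0.05 in edgeR. The named points are the 8 largest rises and 8 largest falls among genes with a mean normalized count of at least 50, led by Vha100-4 and CG5892; genes with fewer reads are not named.

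Genes of digestion were mostly lower in treatment. Of 29 serine proteases of digestion, 24 fell and 4 rose (median log2 -1.27; camera adjusted p = 3.09e-35, and adjusted p = 0.212 with an estimated correlation). Jon66Ci fell from 1131 ± 13.8 to 169.2 ± 11.1 CPM, and Jon65Aii (-2.11) and zetaTry (-2.02) fell as well. Near-identical copies among these proteases may share reads. The proteases and the carbohydrate digestion genes together took 6.10%, 6.37% and 5.97% of reads in the treatment libraries and 10.1%, 10.2% and 10.01% in the control libraries. Among 23 genes of lipid digestion and storage, 13 fell and 5 rose (median -0.23; adjusted p = 4.62e-05, and adjusted p = 0.212 with an estimated correlation). The gut lipase gene mag fell from 4705 ± 121 to 1103 ± 33.5 CPM, the lipid droplet protein gene Lsd-1 fell 7.49-fold and the sterol-binding Npc2d fell by 1.85 on the log2 scale. Carbohydrate digestion was divided, with 10 of 20 genes lower and 6 higher (adjusted p = 0.558). LManV, an alpha-mannosidase, fell by 1.46 while the alpha-glucosidase genes Mal-A7 (2.83-fold) and tobi (5.25-fold) rose. Among 9 genes of the peritrophic matrix and mucins, the lining of the gut lumen, 4 rose and 1 fell (median 0.38; adjusted p = 0.00176, and adjusted p = 0.289 with an estimated correlation), with Peritrophin-15a at 497.4 ± 11.3 against 199.9 ± 11.2 CPM, Peritrophin-15b 2.96-fold and Mur29B 1.75-fold higher. By fry, which does not compare a list with other genes, 32 of the 38 lists passed, among them 18 of the 24 that did not pass camera. The 6 that passed neither were Wnt, Dpp and Hedgehog, Hippo, the mitochondrial respiratory chain, trachea, hemocyte and neuron markers. Counts of members adjusted over the list alone equalled those over all genes tested in these lists, and are given below where they differ.

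Septate junction genes, whose products seal epithelia, tended to be higher in treatment. The list is not limited to genes of the smooth septate junctions of the gut. Of 30 tested, 14 rose and 0 fell (median 0.16; adjusted p = 0.0194, and adjusted p = 0.283 with an estimated correlation). The smooth septate junction genes hoka and Tsp2A rose to 891.4 ± 18.6 from 582.0 ± 6.39 CPM and to 1046 ± 26.1 from 727.1 ± 17.7 CPM, and the adhesion gene Nrg rose 1.83-fold. Of the tricellular junction genes, Gli (2L, 15756001 to 15762755) was at 145.4 ± 1.96 against 108.9 ± 4.63 CPM (1.33-fold; adjusted p = 5.23e-09). The others, bark and M6, rose by 0.25 (SE 0.06) and 0.22 (SE 0.06) on the log2 scale. For dlg1 the values were 30.4 ± 1.23 and 28.9 ± 3.94 CPM (adjusted p = 0.401), although it passed with total-read scaling (adjusted p = 0.00342) and was at -0.03 without control replicate 2. In the adherens junction and polarity list 11 of 14 members rose and 0 fell (12 and 0 adjusted over the list alone), including pyd (0.55), aPKC (0.43) and shg (0.38), without the list passing camera (adjusted p = 0.114; by fry adjusted p = 0.00195).

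Markers of stem cells and of division were higher in treatment. Among 15 intestinal stem cell and enteroblast markers, 11 rose and 1 fell (median 0.55; adjusted p = 0.00583, and adjusted p = 0.283 with an estimated correlation). Sox21a was at 47.8 ± 1.28 against 26.7 ± 2.0 CPM, Delta, the Notch ligand of the stem cell, at 29.1 ± 0.398 against 17.4 ± 1.46, heca rose 1.83-fold and esg 1.35-fold. Of 35 cell cycle genes, 28 rose and 0 fell (median 0.88; adjusted p = 1.61e-05, and adjusted p = 0.207 with an estimated correlation), among them PCNA (2.33-fold), RnrL (1.98-fold) and RnrS (1.63-fold). Of 13 Notch pathway genes, 10 rose and 0 fell (median 0.63; adjusted p = 0.00886, and adjusted p = 0.362 with an estimated correlation), including N (1.99-fold) and E(spl)m3-HLH (1.67-fold). These lists are not independent: Delta, N, E(spl)mbeta-HLH and Su(H) are on both the Notch and the stem cell list, and polo on the cell cycle and stem cell lists.

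Other signalling lists did not pass camera. By fry, JAK-STAT (adjusted p = 0.00193), JNK (0.0227), EGFR (0.0227), insulin and FOXO (0.00102) and cell death and p53 (0.000236) passed. In JAK-STAT 5 of 9 members rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.152). The cytokine gene upd3 was at 25.4 ± 1.18 against 13.4 ± 1.29 CPM and Socs36E rose 1.35-fold. TotM, at 2.24 ± 0.10 against 0.105 ± 0.0933 CPM, rests on few reads. In JNK 6 of 12 rose and 1 fell (adjusted p = 0.260), with Jra (0.48), kay (0.30) and puc (0.29) higher. In EGFR 6 of 13 rose and 2 fell (adjusted p = 0.196), including rho (1.10), pnt (0.81) and spi (0.57). In the Wnt, Dpp and Hedgehog list 3 of 19 rose and 4 fell (adjusted p = 0.973; its median of -0.07 and its test differ in sign), with gbb at 0.62, sax at 0.34 and fz3 at -0.67. In Hippo 4 of 10 rose and 0 fell (adjusted p = 0.668; median -0.01, mean 0.07), the 3 with the smallest adjusted p being sd (0.22), kibra (0.32) and sav (0.24), of which sav lost its call with DESeq2 (adjusted p = 0.0730) and without treatment replicate 2 (0.0797) or control replicate 3 (0.0571). In insulin and FOXO signalling 5 of 15 rose and 6 fell (7 and 7 adjusted over the list alone; adjusted p = 0.0683, and 0.0351 with no filter). ImpL2, a secreted insulin antagonist, rose 3.22-fold and InR 2.29-fold, while foxo fell by 0.30 (SE 0.07), a call lost with total-read scaling (adjusted p = 0.278). Among 12 genes of cell death and p53, 4 rose and 2 fell (adjusted p = 0.407), with Drice (1.65-fold), hid (1.45-fold) and Dronc (1.43-fold) higher.

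**Figure D2:**
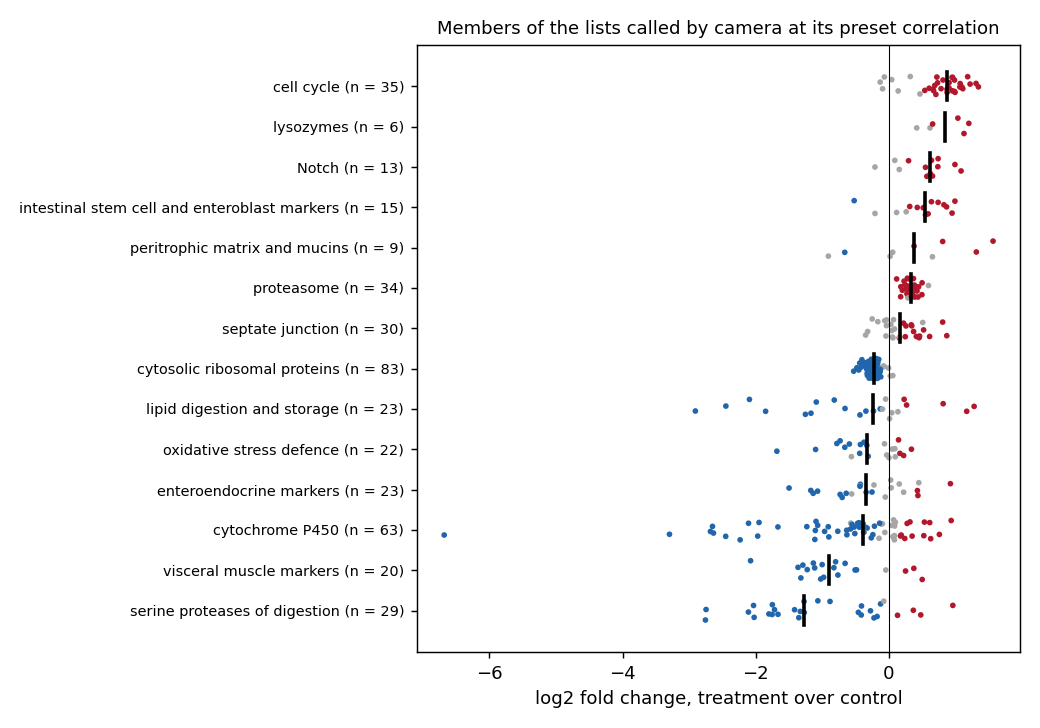
Log2 fold change (treatment over control) of each tested member of the 14 lists that passed camera at its preset correlation, each point a gene (red higher, blue lower, grey not past an adjusted p of 0.05) and each black bar the list's median. Medians run from -1.27 for serine proteases of digestion to 0.88 for the cell cycle; with an estimated correlation 0 of these lists passed.

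Only 5 of 20 antimicrobial peptide genes had enough reads, of which 2 rose and 1 fell (adjusted p = 0.584; median -0.31, mean 0.67). Drs was at 2.02 ± 0.629 against 0.261 ± 0.191 CPM, CecA1 at 2.61 ± 0.642 against 0.841 ± 0.0415. AttD fell by 0.31, a call lost with DESeq2 (adjusted p = 0.0574), with total-read scaling (0.389) and without treatment replicate 1 (0.0755) or control replicate 1 (0.0623). DptA had 7, 3 and 4 reads in treatment and 3, 5 and 7 in control and was not tested. Duox was listed at 0 in all 6 libraries, which cannot tell an unexpressed gene from one whose reads were not counted. In the IMD pathway and peptidoglycan recognition list 5 of 20 rose and 6 fell (adjusted p = 0.730; median 0.02, mean -0.06). PGRP-SC2, an amidase that degrades peptidoglycan, was at 1637 ± 48.1 against 2369 ± 45.2 CPM, PGRP-SC1a fell by 0.84, and key rose by 0.48. Of 6 lysozymes, 4 rose and 0 fell (5 and 0 adjusted over the list alone; median 0.85; adjusted p = 0.0139, and adjusted p = 0.283 with an estimated correlation), with LysC at 1.20, LysD at 1.13 and LysX at 0.66. LysC and LysD are near-identical copies whose reads may be shared.

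Of 63 genes on the cytochrome P450 list, 38 fell and 12 rose (40 and 12 adjusted over the list alone; median -0.38; adjusted p = 2.77e-08, and adjusted p = 0.359 with an estimated correlation). Cyp4d14 (-2.65), Cyp6a21 (-2.23) and Cyp4d8 (-2.11) had the smallest adjusted p. The list includes the cyclophilin genes Cyp1 (0.28, among those that rose) and Cyp40 (-0.09, not called), which are not P450 genes. Among 22 oxidative stress defence genes, 11 fell and 4 rose (median -0.32; adjusted p = 0.00886, adjusted p = 0.567 with an estimated correlation and 0.0511 with total-read scaling). Sod3 fell from 70.0 ± 1.21 to 21.9 ± 1.92 CPM, and the peroxiredoxin Prx2 (-0.78) and Gclm, of glutathione synthesis (-0.73), fell too. Of 26 glutathione transferases, 12 fell and 6 rose (13 and 6 adjusted over the list alone; adjusted p = 0.221), with GstE3 at -1.14, GstO3 at -0.94 and GstD8 at 1.18. Heat shock and chaperone genes went both ways, 13 of 19 higher and 5 lower (14 and 5 adjusted over the list alone; adjusted p = 0.260), with Hsp68 at 1.17, Hsp26 at 0.51 and l(2)efl 3.99-fold lower.

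Proteasome and ribosomal protein genes moved in opposite directions. Of 34 genes on the proteasome list, 32 rose and 0 fell (33 and 0 adjusted over the list alone; median 0.34; adjusted p = 2.30e-06, and adjusted p = 0.362 with an estimated correlation), including Prosalpha6 (1.42-fold), Rpn9 (1.36-fold) and Prosbeta2 (1.34-fold). This list was filled by symbol prefix, so it may hold genes that only share the prefix. Of 83 genes on the cytosolic ribosomal protein list, 77 fell and 0 rose (78 and 0 adjusted over the list alone; median -0.22; adjusted p = 8.29e-05, and adjusted p = 0.669 with an estimated correlation), among them RpL37-1 (-0.48), RpL24-like (-0.53) and RpS29 (-0.45). Of these, RpL24-like encodes a ribosome biogenesis factor and not a protein of the ribosome. The median of the list was -0.02 with total-read scaling, where the median of all genes was 0.22. In the mitochondrial respiratory chain 22 of 66 genes fell and 0 rose (20 and 0 adjusted over the list alone; adjusted p = 0.390), with Cyt-c-p at -0.43, ND-MNLL at -0.36 and UQCR-14 at -0.24, the last not passing with total-read scaling (adjusted p = 0.422). In the V-ATPase list 14 of 20 fell and 2 rose (adjusted p = 0.407; median -0.18, mean 0.09), Vha100-5 (-0.73) and Vha55 (-0.36) falling while Vha100-4 rose.

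Among markers of other gut cell types, visceral muscle markers fell in 16 of 20 cases and rose in 3 (median -0.90; adjusted p = 2.37e-14, and adjusted p = 0.207 with an estimated correlation). The muscle myosin gene Mhc fell from 353.0 ± 6.49 to 141.2 ± 8.78 CPM, Prm by 1.22 and Act87E by 2.08. Enteroendocrine markers fell in 11 of 23 cases and rose in 3 (median -0.34; adjusted p = 0.0491, and adjusted p = 0.553 with an estimated correlation), a call also lost without treatment replicate 2 (adjusted p = 0.0681), control replicate 1 (0.0676) or control replicate 3 (0.0578). The peptide hormone genes Tk (-1.14) and AstA (-0.73) fell, whereas pros, the transcription factor that marks these cells, was at 7.52 ± 0.611 against 6.81 ± 0.539 CPM (adjusted p = 0.328), passing with total-read scaling (adjusted p = 0.0168). The mistakenly listed dmGlut (-1.50) is among the 11 and has the smallest adjusted p on the list, which was not tested without it. Enterocyte markers were divided, 8 of 15 lower and 4 higher (adjusted p = 0.553; median -0.13, mean 0.09), with Vha100-4 (4.77), which is on this list as well, LManV (-1.46) and Amy-p (-0.83) having the smallest adjusted p. Copper cell and anterior midgut markers were 6 higher and 4 lower of 11 (adjusted p = 0.584), with Vha100-4 at 4.77, Mal-A8 at 1.20 and thetaTry at -1.72.

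Lists for tissues next to the gut had few measured members and none passed camera. By fry, ovary and eggshell (adjusted p = 0.0401), fat body (0.000229), Malpighian tubule (0.00115) and hindgut (0.00048) passed. Trachea had 3 of 7 lower (2 adjusted over the list alone; adjusted p = 0.793), namely Gasp (-0.47), trh (-0.89) and verm (-0.49), all of which lost their calls with total-read scaling (adjusted p = 0.135, 0.0621 and 0.228). The call of trh was also lost with DESeq2 (adjusted p = 0.0987) and without treatment replicate 1 (0.0901) or control replicate 1 (0.0709). The call of verm was lost with DESeq2 (0.139), with no filter (0.0580) and without any 1 of treatment replicates 1 (0.0634), 2 (0.0842) and 3 (0.121) and control replicates 1 (0.0844) and 2 (0.177). Ovary and eggshell had 1 of 5 higher, piwi at 1.32 (adjusted p = 0.584). Fat body had 3 higher and 3 lower of 6 (adjusted p = 0.509), with Yp1 at 0.70, FASN1 at -1.09 and Cyp4g1 at 0.0283 ± 0.0490 against 3.42 ± 0.518 CPM. Cyp4g1, better known as an oenocyte gene, had only 0, 0 and 1 reads in treatment and 42, 44 and 54 in control. Hemocyte markers were 2 higher and 3 lower of 7 (adjusted p = 0.973; median -0.29, mean 0.58). Of these, lz (4.07 ± 0.789 against 0.270 ± 0.180 CPM) and PPO1 (1.97 ± 0.434 against 0.339 ± 0.0184) rose and Ppn fell by 0.89. Malpighian tubule markers were 2 higher and 2 lower of 8 (3 and 2 adjusted over the list alone; adjusted p = 0.201, and 0.00658 among genes with a mean count of at least 100; median -0.18, mean 0.03), with Picot at -1.55, Fst at -0.41 and Oatp58Db at 1.06, the last losing its call with DESeq2 (adjusted p = 0.0856) and without treatment replicate 2 (0.0810) or 3 (0.0542) or control replicate 1 (0.0557) or 3 (0.0800). Hindgut markers were 2 lower of 4, bowl at -0.97 and NaCP60E at -0.80 (adjusted p = 0.407). Neuron markers were 2 higher of 4, elav at 1.22 and onecut at 1.18 (adjusted p = 0.584).

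**Figure D3:**
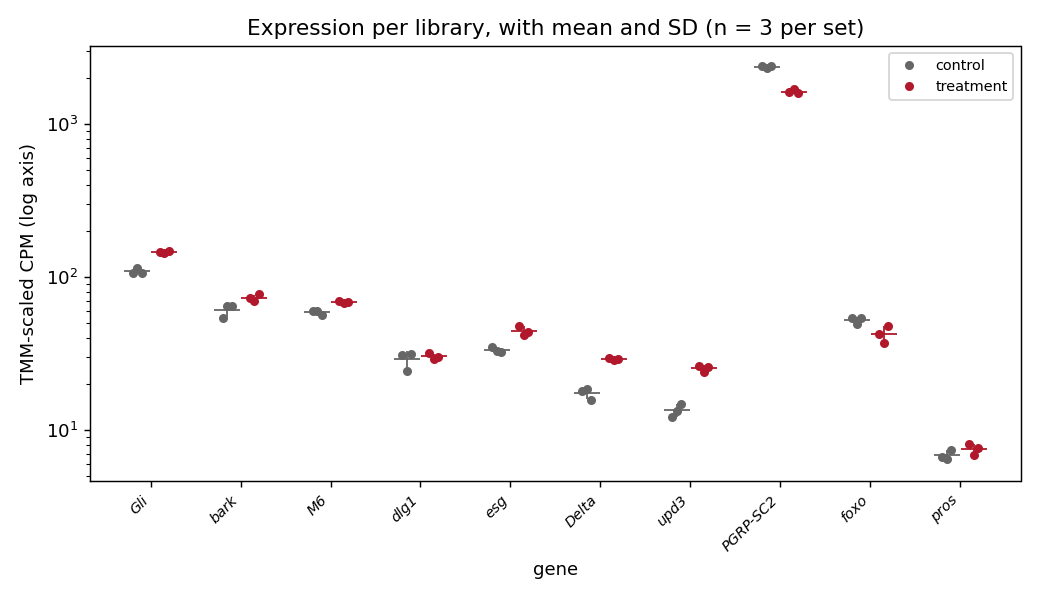
TMM-scaled CPM (log axis) in each library for the genes named whatever their value and with enough reads, points for single libraries and bars for mean and SD (n = 3 per set; grey control, red treatment). Gli lies at 145.4 in treatment against 108.9 in control, while the sets overlap for dlg1.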

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

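Scaling by total reads was chosen after the result was seen; the other alternatives were planned. Of 4000 changed genes, 3923 were shared with RLE size factors (3999 called) and 3318 with DESeq2 (3323 called). Leaving out 1 library gave 3564 to 3809 genes and 13 to 14 lists. Counts moved by over 1.5 times with total-read scaling (4127 higher, 1076 lower), a 2-fold minimum (590, with 196 higher and 394 lower) and transcripts in place of genes (7962 of 15803, with 4076 higher and 3886 lower), where more features were tested and isoforms share reads. With an estimated correlation 0 lists passed, where 14 had. The estimates were 0.0080 for the cell cycle and 0.0092 for septate junction, below the preset 0.01. A higher correlation therefore cannot account for the loss of these calls. The other lists that had passed had estimates above the preset value, but whether that accounts for their loss was not tested. Lists that never passed changed direction, and the cause was not tested: with total-read scaling IMD (adjusted p = 0.970), Wnt, Dpp and Hedgehog (0.918), the respiratory chain (0.905) and hemocyte markers (0.918); with no filter Wnt, Dpp and Hedgehog (0.970) and hemocyte markers (0.872); at a mean count of at least 100 hemocyte markers (0.348). Leaving out 1 library gave 0.818 to 0.965 for Wnt, Dpp and Hedgehog, 0.870 to 0.988 for hemocyte markers, and log2 fold changes of -0.027 to 0.15 for dlg1. Over all settings, values of named genes kept direction and side of the threshold in 1454 cases, lost it in 27, gained it in 2 and turned in 1; for lists the counts were 419, 18, 2 and 12. To look for pairing, deviations of log2 CPM from each set's mean were correlated between treatment and control libraries. These deviations correlated at 0.01, 0.09 and 0.02 for same-numbered replicates, and at -0.09 to 0.08 for differently numbered ones. These few values show no clear pairing by number and cannot exclude it. A block on replicate number gave 4116 genes and 14 lists. Pseudocounts and unmatched random lists apply to normalized values or group means and were not run. In data simulated at these depths and replicate numbers 64% of 1.3-fold changes were called, and what depth alone limits was not tested.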

Other observations

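The genes of the next paragraph, the tests of library scaling and of stem cell number, and the final bounds of both tests were chosen after the results were seen.

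The homeotic gene lab, which specifies acid-secreting copper cells of the middle midgut, was at 2.74 ± 0.173 CPM in treatment and 0.415 ± 0.0830 in control (log2 2.70, SE 0.31), beside the rise of Vha100-4. The neighbouring alpha-glucosidase genes Mal-A6, Mal-A7 and Mal-A8 rose 2.64-, 2.83- and 2.29-fold. Mal-A7 (2R, 4357054 to 4359802) and Mal-A8 (2R, 4359488 to 4361466) overlap on opposite strands in the deposited coordinates. The rule for antisense reads is not given, so their rises may not be independent. Ldh, lactate dehydrogenase, was at 237.1 ± 9.66 against 90.9 ± 0.746 CPM. In treatment replicate 2 alone srl stood at 157.3 CPM, against 15.3 and 16.2 in the other treatment libraries. The control libraries varied as well, at 29.0 ± 13.5 CPM (treatment against control, adjusted p = 0.0724).

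The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 4000 genes and the highest other split 0 (1 of 10 splits as large). Every other split mixes the sets, so the difference between sets enters the spread within its groups. Few gene calls could then arise, and the 0 decides nothing. For lists at the preset correlation the real split called 14 and the highest other 12 (1 of 10 as large). The mixed splits called 4 to 12 lists with 0 genes changed, so lists were called at this setting where no gene passed.

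The fall of cytosolic ribosomal protein genes (median log2 -0.22) was weighed first. A trend with transcript length and expression was argued against: after its removal the median was -0.17 (quartiles -0.23 and -0.13, 81 of 83 genes below 0). With total reads alone the median was -0.019, which by the bound first written favoured scaling as the cause. That scaling moves all genes alike, so the test decides nothing. Relative to the median of all genes these genes lay at -0.24 under both scalings. They took 10.1%, 10.7% and 9.99% of reads in the treatment libraries and 10.6%, 10.6% and 10.2% in the control libraries, which overlap. The named difference in age stays open and untested here.

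For the rise of cell cycle genes (median 0.88), low read counts were argued against, since 10000 random lists of equal expression had a typical median of 0.020 and a highest of 0.29. More stem cells and enteroblasts in an unaltered cycling state may contribute. The cell cycle median exceeded that of the stem cell list by 0.31 with shared genes left out of both (0.85 against 0.54; bootstrap 95% interval 0.07 to 0.61, over 34 and 14 genes). By the bound first written, an interval above 0, this counted against that explanation. The bound was then changed, after the value was seen, to ask also that no marker reach this cell cycle median of 0.85, because markers read in other gut cells rise less than their cells do; 2 of 14 reached it, and the question is left open.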
